A study of Mus musculus with 18 samples.

How the data were processed

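Liver RNA from 18 male db/db mice was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, 1 array per mouse. The db/db mouse lacks a working long form of the leptin receptor and becomes obese and diabetic. All mice were kept under 12 h of light and 12 h of dark, and the regimens began at 4 months of age and lasted 7 months. In intermittent fasting (IF) food was withheld for 24 h on alternate days, each fast starting at night. Livers were taken at zeitgeber time (ZT) 9, in the light period, or ZT 21, in the dark period, from mice fed ad libitum, from IF mice in the feeding phase and from IF mice in the fasting phase. This gave 6 groups of 3 arrays. The labels describe 3 separate mice per group, so the spread within a group is spread between animals.

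The deposited values are log2 intensities per transcript cluster, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. Those notes also name Transcriptome Analysis Console and R 2.15.3 for the authors' statistics. RMA corrects background, quantile-normalises probe intensities and summarises the probes of a cluster; the software version and the genome build of the probe annotation are not given in the sources used here. The table holds 41345 clusters with values from 1.50 to 13.69 and no missing values. Its arrays were not scaled further. Detection calls and background values were not used here, so the level below which a value is mostly background is not known. The number of animals limits the precision.

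Clusters were named through GEO's platform annotation, with symbols updated by Entrez ID from a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of the clusters, 23521 had 1 gene symbol, 1814 had several and 16010 had none; only the first kind were named. The Entrez ID of 23328 of them was in the RefSeq table, and the other 193 kept the platform's symbol. The 1082 genes with more than 1 cluster were represented by the cluster with the highest mean over all arrays, which left 22180 genes. Among the genes named, another cluster went in the other direction for Mid1ip1, for Hspb1 (0.019 ± 0.12 in the fasting phase and 0.0043 ± 0.128 at ZT 21) and for Cd9 (-0.19 ± 0.101 by time in the IF fasting phase and 0.017 ± 0.101 in the fasting phase at ZT 9), in each case at a lower mean than the cluster used. A gene was tested if at least 3 arrays lay at or above the 40th percentile of all genes on that array, a log2 value of 4.84 to 4.91. This left 14094 genes. Probes shared between close relatives, such as members of the Cyp2b, Saa and Sult2a families, can mix their signals.

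Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. After the authors' description of their model, the 3 main effects came from an additive model over all 18 arrays with terms for IF, for the fasting phase and for ZT 21 (14 residual degrees of freedom). Because the fasting phase has its own term, the IF term compares the IF feeding phase with ad libitum feeding. Both interactions with time and the differences within 1 time or 1 feeding group came from a model with a mean for each of the 6 groups (12 residual degrees of freedom). Log2 differences are given ± SE and group means ± SD (n = 3).

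Gene lists of 25 processes and 12 cell types were fixed before the data were examined, as were the tests and the rule for naming genes. Their 717 entries gave 646 with a gene in the table, 3 of them through a synonym, and 606 that were tested. The 33 lists with at least 5 tested genes were tested with camera, a competitive test, at a preset correlation of 0.01 between genes, with p-values adjusted over the lists of a comparison. Counts of list members past the threshold are given over all tested genes and adjusted over the list alone. Of 396 list tests 186 passed; with a correlation estimated from the data 3 of these held, all for the circadian clock list, namely in the time of day effect, in ad libitum feeding by time and in the IF fasting phase by time. The alternative fry, which asks whether a list's genes move on balance in 1 direction, called 109.

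The genes named are, for each main effect, the 10 with the largest positive and the 10 with the largest negative log2 difference among those past the threshold, or the 10 with the smallest p where fewer than 10 passed. Predicted genes and those of the Olfr, Mir, Snor, Ig and Tcr families were counted but not named. For each interaction the 6 genes with the smallest p are named, for each difference within a time or group the 4 with the largest absolute log2 difference that passed, and for each list described the 4 members with the smallest p. Cyp7a1, Cyp8b1, Baat, Abcb11, Slc10a1, Nr1h4, Nr0b2, Gpbar1, Fgf21, Cpt1a, Pck1, Srebf1, Arntl, Per2, Dbp and Lepr were always to be named; Per2 had no cluster with that symbol alone and was not analysed here.

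The models were tested on simulated data (14094 genes, 3 runs) that kept only the real genes' means and spreads. Genes changed 1.5-fold were recovered at 86.0% for the IF effect, 92.0% for the fasting phase and 90.0% for time of day. At 2-fold the interaction models recovered 78.0% (IF by time) and 72.7% (fasting phase by time), and the differences within a time or group from 89.3% to 96.0%. In 20 simulations of the fasting phase effect camera called all 20 lists of 20 genes shifted by 1.5-fold, and 3 of 660 unshifted lists. False calls for lists of correlated genes, and recovery with interactions or outlying arrays, stay unknown.

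Each comparison was repeated with no filter, with a stricter filter (60th percentile, 9586 genes), with every transcript cluster as its own feature, with a trended and robust variance, with array weights, with the replicate number as a block, after quantile normalization of the deposited values, with only the groups compared, and without each array in turn. The main effects were repeated in the 6-group model and with a 1.5-fold minimum, and the IF effect also with both IF phases against ad libitum feeding. The rule the authors describe was applied to the IF effect: a likelihood ratio test of the whole model at a false discovery rate under 0.3, then p under 0.05 and a change over 1.5-fold. Leaving out the 2 arrays that lie far from the rest, or these and the third array with high Saa2, was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.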

Results

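Gene expression was measured in the liver of male db/db mice that either ate ad libitum or lived under long-term intermittent fasting (IF), with 18 arrays in 6 groups of 3 mice. The 2 times of collection were ZT 9 and ZT 21, and IF livers came from a feeding phase and a fasting phase. The design asks how the liver transcriptome differed by regimen, by feeding state within the regimen and by time of day, in a series about the gut-liver axis and diabetic retinopathy. Correlations between arrays over all clusters ran from 0.945 to 0.993 across the 153 pairs, and from 0.962 to 0.993 within groups; no pair held identical values in more than 0.0355% of clusters. The first principal component held 31.8% of the variance. Arrays 2 and 3 of the IF feeding group at ZT 9 lay at 49.3 and 31.4 on it, and the other 16 between -16.5 and 9.09.

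Those 2 arrays, and array 1 of the IF fasting group at ZT 21, carried high levels of neutrophil and acute phase transcripts. Saa2, a serum amyloid gene of the acute phase, had log2 values of 13.26, 12.50 and 12.86 on these 3 arrays and between 7.59 and 10.48 on the other 15. The mean deviation of the 11 neutrophil genes from their average over all arrays was 4.46, 3.43 and 1.76 on them, and -0.82 to -0.39 elsewhere. Fatty acid oxidation genes were lowest on the first pair, with mean deviations of -0.93 and -0.64. Many results that move without these 3 arrays, which stand apart, are given both ways. The IF feeding group at ZT 9 then has 1 array, assumed to vary like other groups.

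**Figure D1:**
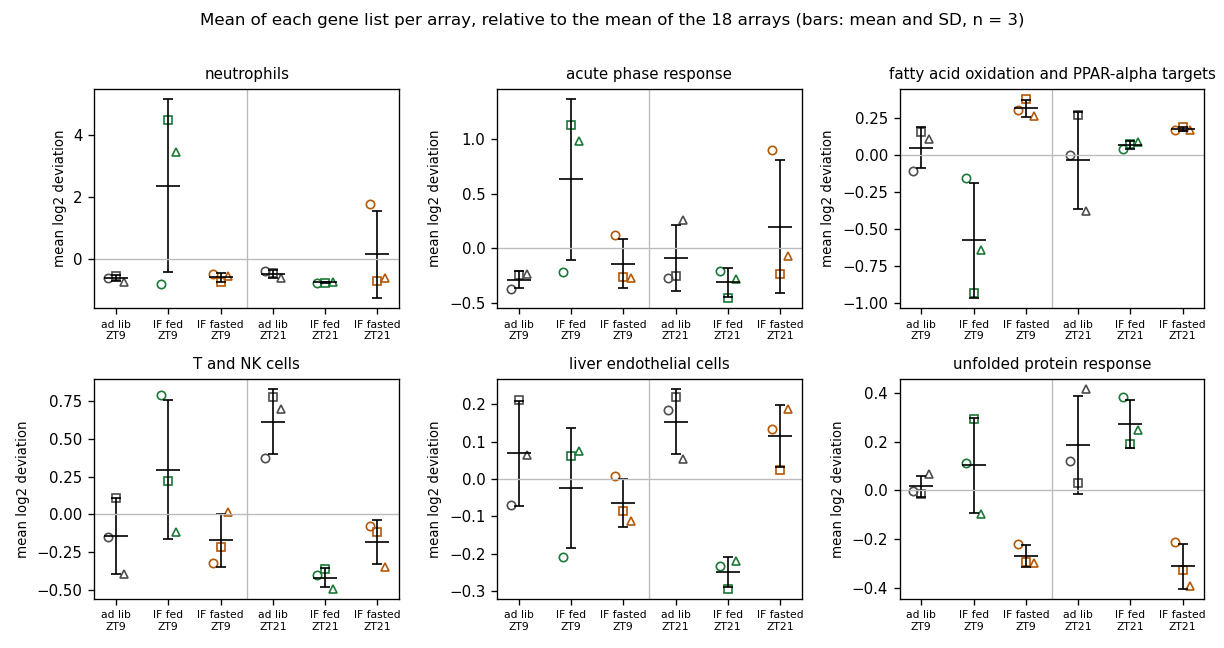
Mean log2 deviation of 6 gene lists from their average over the 18 arrays (vertical axes), with 1 point per array (circle, square and triangle for arrays 1, 2 and 3) and bars for the group mean and SD, n = 3, by group (horizontal axes). Neutrophil genes reach 4.46 and 3.43 on arrays 2 and 3 of the IF feeding group at ZT 9, where fatty acid oxidation genes fall to -0.93 and -0.64.

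The comparison of ZT 21 with ZT 9, over all 3 feeding groups, was led by the core circadian clock. The transcriptional activators Npas2 (transcript cluster 17212087) and Arntl (17481960) rose at ZT 21 by 3.12 ± 0.116 and 2.47 ± 0.202 on the log2 scale (8.69-fold and 5.53-fold), while the clock output gene Dbp (17477979) fell by 2.70 ± 0.111, or 6.49-fold. In ad libitum livers Npas2 went from 4.97 ± 0.17 (SD, n = 3) at ZT 9 to 8.26 ± 0.168 at ZT 21, and Dbp from 9.72 ± 0.0708 to 6.67 ± 0.0624. The repressors Nr1d1 and Nr1d2 (the REV-ERB receptors) fell by 1.80 ± 0.14 and 1.89 ± 0.0969, and Per3 and Ciart fell by 1.81 ± 0.0902 and 2.08 ± 0.14. Of 16 clock genes tested, 5 rose, 8 fell and 3 did not pass, over all genes as well as adjusted over the list alone. As a set they were lower (median -0.33, camera adjusted p = 0.000614, and adjusted p = 0.0263 with an estimated correlation), although 5 members rose.

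Beyond the clock, the genes with the largest rises at ZT 21 were Chka (choline kinase alpha, 2.05 ± 0.124), the cell cycle inhibitor Cdkn1a (2.04 ± 0.278), the glycogen targeting subunit Ppp1r3c (1.76 ± 0.224), the mitochondrial chaperone Clpx (1.49 ± 0.118), Slc34a2 (1.42 ± 0.288), Spon2 (1.34 ± 0.248), Dhrs9 (1.28 ± 0.119) and the pyruvate dehydrogenase kinase Pdk4 (1.17 ± 0.204). Their limma adjusted p-values ran from 1.27e-08 for Chka to 0.00943 for Slc34a2. Usp2 fell by 1.57 ± 0.14, Upp2 by 1.41 ± 0.204, Wee1 by 1.41 ± 0.217, Tef by 1.26 ± 0.0797 and Gpcpd1 by 1.11 ± 0.14. Slc34a2 stood at 1.28 with a limma adjusted p of 0.0594 once the 3 arrays that stand apart were left out.

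Among 24 genes of gluconeogenesis and fasting regulation, 3 fell at ZT 21 and none rose (6 lower and 1 higher adjusted over the list alone). Per1 fell by 0.87 ± 0.124, Foxo3 by 0.30 ± 0.0566 and Pck1, the gene of the gluconeogenic enzyme PEPCK, by 0.35 ± 0.0802, while Foxo1 had -0.25 ± 0.0708 with a limma adjusted p of 0.0705. The list's camera adjusted p was 0.00596 (adjusted p = 0.37 with an estimated correlation). In the ketone body list of 5 genes, the transporters Slc16a1 (0.53 ± 0.0908) and Slc16a6 (0.33 ± 0.0816) rose, also adjusted over the list alone, but Slc16a6 did not pass in 10 of 18 fits with 1 array left out. Its camera adjusted p of 0.00926 (adjusted p = 0.565 with an estimated correlation) became 0.137 without the 3 arrays. Acat1 (0.15 ± 0.072) and Slc16a7 (0.07 ± 0.104) did not pass.

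In bile acid transport and sensing 3 of 21 genes fell at ZT 21 (3 lower and 1 higher adjusted over the list alone). The sterol transporters Abcg8 and Abcg5 fell by 0.41 ± 0.0768 and 0.42 ± 0.0849, and Nr0b2, which encodes the bile acid responsive repressor SHP, fell by 0.60 ± 0.141. In bile acid synthesis Hsd3b7 rose by 0.27 ± 0.0523, 1 of 17 (2 adjusted over the list alone). Neither list was called (camera adjusted p = 0.577 and 0.116). Cyp8b1, the sterol 12-alpha hydroxylase, had 0.81 ± 0.226 with a limma adjusted p of 0.0653. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.48 ± 0.25, Abcb11 0.25 ± 0.0947, Baat 0.21 ± 0.115, Nr1h4 -0.14 ± 0.0667, Gpbar1 0.08 ± 0.0567 and Slc10a1 -0.0084 ± 0.0414. Fgf21 (0.22 ± 0.21), Cpt1a (-0.21 ± 0.0736), Srebf1 (-0.08 ± 0.0803) and Lepr (0.14 ± 0.175) did not pass either. In all, limma with Benjamini-Hochberg adjustment called 401 genes by time, 253 higher and 148 lower, of which 76 changed by more than 1.5-fold.

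**Figure D2:**
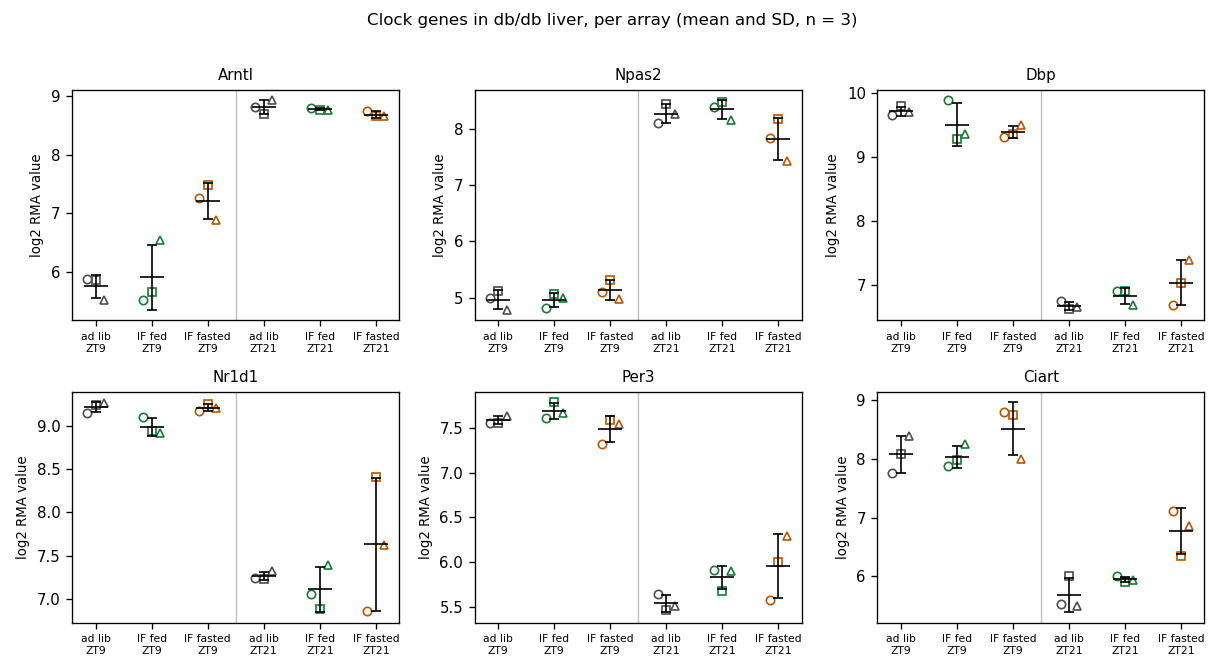
Log2 RMA values (vertical axes) of 6 clock genes on each array by group (horizontal axes), with circles, squares and triangles for arrays 1, 2 and 3 and bars for the group mean and SD, n = 3. Arntl lies between 6.88 and 7.48 in the IF fasting group at ZT 9, above the ad libitum arrays at that time (5.52 to 5.87) and below all arrays at ZT 21 (8.65 to 8.93).

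The time of day difference was then taken within each feeding group. In the IF groups ZT 21 and ZT 9 also differed in the time since food was removed or given, because each fast started at night. In ad libitum livers the 4 largest changes were Npas2 (3.29 ± 0.16), Arntl (3.06 ± 0.203), Dbp (-3.05 ± 0.16) and Chka (2.45 ± 0.162). Of the clock genes 5 rose and 7 fell there (5 and 10 adjusted over the list alone). Nr1d2 fell by 2.12 ± 0.117 and Per3 by 2.04 ± 0.135. For the clock list camera gave an adjusted p of 0.000606 (adjusted p = 0.0307 with an estimated correlation). Genes of T and NK cells were higher at ZT 21 in these mice as a set, with a median of 0.61: Nkg7 rose by 1.27 ± 0.281 and, adjusted over the list alone, 6 of 9 were higher, with Gzmb at 0.93 ± 0.227, Cd3g at 1.42 ± 0.39 and Cd4 at 0.60 ± 0.17. That set's camera adjusted p was 7.69e-06 (adjusted p = 0.325 with an estimated correlation). In all 215 genes passed in ad libitum livers, 141 higher and 74 lower. After quantile normalization of the arrays the split was 110 higher and 90 lower, and with 1 array left out 114 to 286 passed.

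In the IF fasting phase Npas2 rose by 2.68 ± 0.16, and Dbp fell by 2.36 ± 0.16, Ciart by 1.75 ± 0.227 and Nr1d1 by 1.58 ± 0.245. Of the clock list 2 genes rose and 6 fell (4 and 9 adjusted over the list alone). Nr1d2 fell by 1.46 ± 0.117 and Per3 by 1.53 ± 0.135. By camera the clock list had an adjusted p of 7.69e-05 (adjusted p = 0.0154 with an estimated correlation). Cholesterol synthesis genes had a median of 0.52 at ZT 21 over ZT 9 in this phase, with 0 of 19 past the threshold over all genes in limma, 3 higher adjusted over the list alone and a fry adjusted p of 0.256. The leading members were Fdps (0.89 ± 0.255), Hmgcs1 (0.85 ± 0.254), Insig1 (0.55 ± 0.177) and Pmvk (0.80 ± 0.278). Their camera adjusted p was 5.68e-07 (adjusted p = 0.614 with an estimated correlation), and without the 3 arrays 5 passed with a list median of 0.80. Kupffer cell genes had a median of 0.53 (0.46 without the 3 arrays), with 4 of 18 higher adjusted over the list alone and 0 over all genes. For Kupffer cell genes camera gave an adjusted p of 5.26e-06 (adjusted p = 0.614 with an estimated correlation). Cd68 stood at 0.72 ± 0.203, Cd9 at 0.42 ± 0.129, C1qb at 0.79 ± 0.267 and Vsig4 at 0.84 ± 0.283. Altogether 72 genes passed, 38 higher and 34 lower, and 23 to 110 with 1 array left out.

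In the IF feeding phase, where ZT 9 holds the arrays with neutrophil transcripts, the 4 largest changes by time were Ngp (-4.32 ± 1.26), S100a8 (-4.29 ± 1.13), Cyp2b13 (4.07 ± 0.963) and Saa2 (-3.59 ± 1.01). With the 3 arrays left out these stood at -0.22, -0.53, 1.09 and -1.27, and none passed. Of 11 neutrophil genes 9 fell (11 lower adjusted over the list alone). Csf3r fell by 1.55 ± 0.413, Mpo by 3.00 ± 0.836 and S100a9 by 2.67 ± 0.769. By camera the neutrophil list had an adjusted p of 2.86e-06 (adjusted p = 0.356 with an estimated correlation). Their median went from -3.22 to 0.033 without those arrays. Of the clock list 5 genes rose and 7 fell (6 and 7 adjusted over the list alone). Npas2 rose by 3.38 ± 0.16 and Arntl by 2.87 ± 0.203, and Nr1d2 fell by 2.08 ± 0.117 and Dbp by 2.69 ± 0.16. The 4 stood at 3.53, 3.26, -2.22 and -3.07 without the 3 arrays. The clock list as a set was not called there (camera adjusted p = 0.247).

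Of 32 fatty acid oxidation genes 17 rose at ZT 21 in the IF feeding phase and none fell (23 and 1 adjusted over the list alone). Cpt2 rose by 0.61 ± 0.0826, Pdk4 by 1.83 ± 0.311, Etfdh by 0.45 ± 0.0826 and Acot4 by 0.89 ± 0.179. Their median was 0.58 (camera adjusted p = 5.97e-10; adjusted p = 0.356 with an estimated correlation) and 0.14 without the 3 arrays, and the neutrophil genes moved in the opposite direction across the same arrays. Of 18 Kupffer cell genes 13 fell (15 adjusted over the list alone). C1qa fell by 1.21 ± 0.139, Clec4f by 1.25 ± 0.213, Cd5l by 1.82 ± 0.313 and C1qc by 1.18 ± 0.23. The median went from -1.20 to -0.63 without those arrays. By camera Kupffer cell genes had an adjusted p of 5.26e-09 (adjusted p = 0.247 with an estimated correlation). In total 1697 genes passed (654 higher and 1043 lower), with 205 without the 3 arrays and 691 to 2565 with 1 array left out.

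Feeding state within the IF regimen was compared over both times, as the fasting phase against the feeding phase. Sdf2l1 (transcript cluster 17328625), a chaperone cofactor, fell by 1.78 ± 0.254 (3.44-fold) and Hyou1 (17516564), a chaperone of the same compartment, by 1.20 ± 0.153. The lipogenic regulators Mid1ip1 (17533282) and Srebf1 fell by 1.19 ± 0.0905 and 0.86 ± 0.0983, with limma adjusted p-values of 2.5e-06 and 0.000159. The lipid droplet coat gene Plin4 (17346125) rose by 1.64 ± 0.21 (3.12-fold) and Cpt1a, which admits fatty acids to mitochondria, by 0.50 ± 0.0901. Other clusters of Mid1ip1 gave -0.50 ± 0.127 and 0.09 ± 0.0891 at mean log2 values of 6.35 and 5.58, against 8.17 for the cluster used.

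Of 22 genes of the unfolded protein response 11 fell and none rose (16 lower and 1 higher adjusted over the list alone). Calr fell by 0.70 ± 0.0797, Pdia3 by 0.61 ± 0.0779 and Pdia6 by 0.91 ± 0.12. The camera adjusted p was 3.1e-13 (adjusted p = 0.273 with an estimated correlation; fry adjusted p = 0.000835), and the median of -0.43 was -0.55 without the 3 arrays. The heat shock list of 10 genes had 3 that fell (4 adjusted over the list alone). Hsp90aa1 fell by 0.61 ± 0.106, Hsph1 by 0.77 ± 0.171 and Chordc1 by 0.52 ± 0.127, with Hspb1 at -0.94 ± 0.285 and a limma adjusted p of 0.0625. The list's camera adjusted p was 0.00139 (adjusted p = 0.63 with an estimated correlation).

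Among 27 genes of lipogenesis and glycolysis 5 fell and none rose (5 lower and 3 higher adjusted over the list alone): next to Mid1ip1 and Srebf1 were Pnpla3, which fell by 1.27 ± 0.299, and Aacs, by 0.69 ± 0.138. The list as a set was not called (camera adjusted p = 0.246), with a median of -0.033. Cholesterol synthesis and uptake had 4 of 19 genes that fell (13 adjusted over the list alone). Insig1 fell by 0.82 ± 0.156, Stard4 by 0.68 ± 0.169, Sc5d by 0.39 ± 0.104 and Mvd by 0.91 ± 0.253 (Mvd did not pass in 12 of 18 fits with 1 array left out). For that list the camera adjusted p was 3.16e-07 (adjusted p = 0.675 with an estimated correlation), and 0.0523 without the 3 arrays, where 0 members passed in limma and the median was -0.20.

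Fatty acid oxidation genes moved the other way: 7 of 32 rose (16 adjusted over the list alone). Ppara rose by 0.52 ± 0.086, Plin5 by 0.98 ± 0.163 and Eci2 by 0.46 ± 0.0856. For fatty acid oxidation camera gave an adjusted p of 2.44e-13 (adjusted p = 0.583 with an estimated correlation). Their median was 0.47, and 0.16 without the 3 arrays, on which neutrophil genes were high and 2 of which belong to the feeding phase. Lipid droplet genes rose in 4 of 14 cases (5 adjusted over the list alone): Plin4, the triglyceride lipase Pnpla2 by 0.54 ± 0.0654, Fitm2 by 0.53 ± 0.124 and G0s2 by 0.86 ± 0.234. By camera lipid droplet genes had an adjusted p of 0.000103 (adjusted p = 0.649 with an estimated correlation). That list had a camera adjusted p of 0.0573 without the 3 arrays.

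In the list of gluconeogenesis and fasting regulators 3 of 24 genes rose in the fasting phase (10 higher and 1 lower adjusted over the list alone). Foxo1 rose by 0.39 ± 0.0867, the clock gene Per1 by 0.59 ± 0.152 and Fkbp5 by 0.65 ± 0.171, while Slc37a4 had 0.29 ± 0.0829 with a limma adjusted p of 0.0509. For the gluconeogenesis list camera gave an adjusted p of 0.00586 (adjusted p = 0.415 with an estimated correlation). Xenobiotic metabolism had 3 of 25 genes that rose (5 higher and 1 lower adjusted over the list alone). Cyp3a25 rose by 1.17 ± 0.175, Cyp2b10 by 1.70 ± 0.456 and the nuclear receptor Nr1i2 by 0.32 ± 0.0865, with Nr1i3 at 0.60 ± 0.174. That list's camera adjusted p of 0.0043 (adjusted p = 0.675 with an estimated correlation) became 0.497 without the 3 arrays. Of the clock list Per1 and Ciart (0.65 ± 0.172) rose (3 higher adjusted over the list alone), with Hlf at 0.37 ± 0.117 and Nr1d2 at 0.31 ± 0.119. With 1 array left out Ciart and Nr1i2 did not pass in 9 of 18 fits each, Cyp2b10 in 8, Per1 in 7 and Fkbp5 in 6. By camera the clock list had an adjusted p of 0.0251 (adjusted p = 0.406 with an estimated correlation). The set had a camera adjusted p of 0.0803 without the 3 arrays.

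Further genes that rose most were Elovl3 (1.49 ± 0.324), Cdkn1a (1.40 ± 0.34), Rab30 (1.13 ± 0.155), Angptl4 (1.09 ± 0.253), Glod5 (1.08 ± 0.304), Pnldc1 (1.08 ± 0.154) and Npnt (1.07 ± 0.136). S100a6 (-1.32 ± 0.32), Dhrs9 (-1.19 ± 0.146), Rnu3a (-1.11 ± 0.162), Angptl8 (-1.10 ± 0.232), Mybl1 (-1.10 ± 0.25) and Krt18 (-1.08 ± 0.167) were among those that fell most. Without the 3 arrays Cyp2b10 (1.02), Elovl3 (0.95), Cdkn1a (0.89), Angptl4 (0.67) and Glod5 (0.88) no longer passed. Per1, Ciart, Foxo1, Nr1i2, G0s2 and Fitm2 did not either, nor did Glod5 in 13 of 18 fits with 1 array left out. Of the genes always named, Fgf21 (0.83 ± 0.257, limma adjusted p = 0.0697), Pck1 (0.33 ± 0.0983), Cyp8b1 (0.66 ± 0.277), Cyp7a1 (0.29 ± 0.306), Abcb11 (-0.35 ± 0.116), Slc10a1 (0.17 ± 0.0507), Nr1h4 (0.22 ± 0.0817), Baat (0.11 ± 0.141), Gpbar1 (0.09 ± 0.0694), Nr0b2 (-0.016 ± 0.173), Arntl (0.60 ± 0.248), Dbp (0.04 ± 0.136) and Lepr (0.05 ± 0.215) did not pass. Cyp7a1 stood at 0.96 without the 3 arrays but 0.55 without the 2 at ZT 9. The third array left out held 9.03 for Cyp7a1, against 10.63 and 10.97 in the rest of its group.

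The neutrophil and Kupffer cell lists were called between the phases by camera at its preset correlation only. The neutrophil list had a median of -0.99 in fasting against feeding, with 0 of 11 past the threshold in limma. Mpo led it (-1.14 ± 0.723), with Ltf (-1.37 ± 0.886), Cxcr2 (-0.77 ± 0.517) and Elane (-1.19 ± 0.817) next. Kupffer cell genes had a median of -0.34 with 0 of 18 past it. Leading them were Ccr2 (-0.78 ± 0.305), Lyz2 (-0.73 ± 0.334), Cd68 (-0.45 ± 0.212) and Cd9 (-0.29 ± 0.14). Camera gave each list an adjusted p of 0.0251 (adjusted p = 0.675 with an estimated correlation). By fry these lists had adjusted p-values of 0.382 and 0.358. Their medians were 0.21 and -0.10 without the 3 arrays. In all, limma called 797 genes between the phases, 414 higher and 383 lower in fasting, 151 of them by more than 1.5-fold; 514 passed without the 3 arrays, 437 to 857 with 1 array left out and 1398 in the 6-group model.

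**Figure D3:**
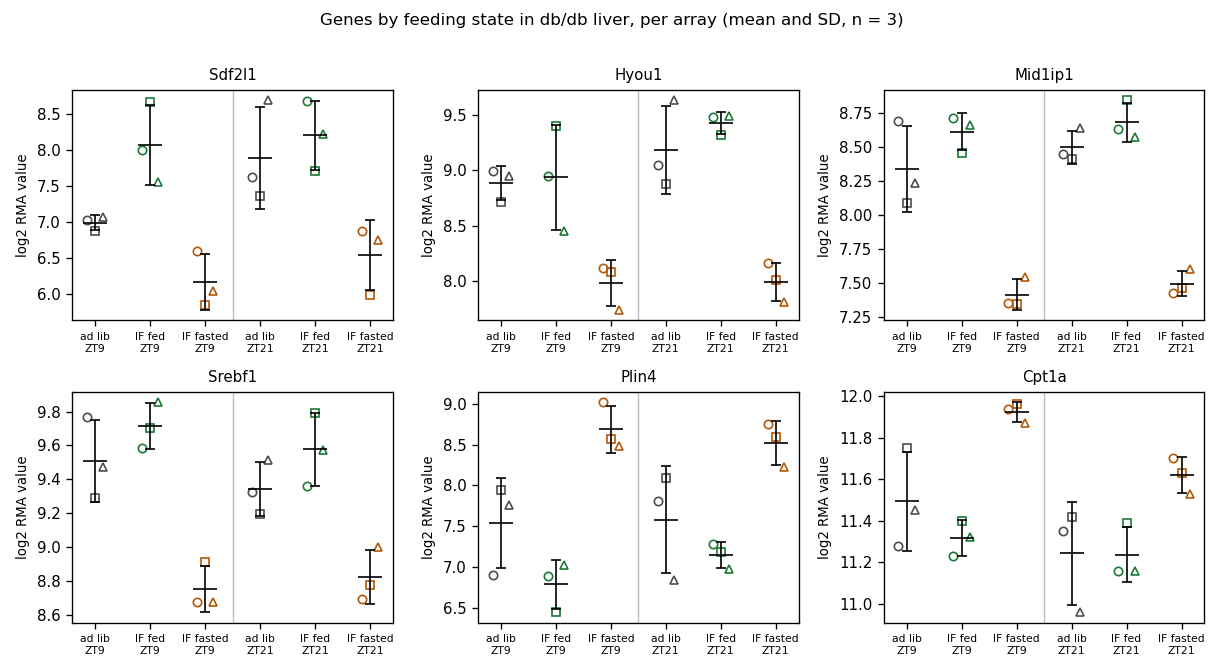
Log2 RMA values (vertical axes) of 6 genes on each array by group (horizontal axes), with circles, squares and triangles for arrays 1, 2 and 3 and bars for the group mean and SD, n = 3. Mid1ip1 lies between 7.35 and 7.60 on the 6 IF fasting arrays and between 8.09 and 8.84 on the other 12, and Srebf1 between 8.67 and 9.003 against 9.20 to 9.86.

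At ZT 9 alone the fasting phase was compared with the feeding phase. Of 32 fatty acid oxidation genes 28 rose (29 adjusted over the list alone). Acot3 rose by 2.15 ± 0.327, Acot4 by 1.45 ± 0.179, Cpt2 by 0.60 ± 0.0826 and Etfdh by 0.56 ± 0.0826. For fatty acid oxidation camera gave an adjusted p of 9.27e-18. The median of 0.76 was 0.34 without the 3 arrays, and 8 members then rose. Cholesterol synthesis and uptake fell in 15 of 19 genes (18 adjusted over the list alone). Insig1 fell by 1.23 ± 0.177, Hmgcs1 by 1.33 ± 0.254, Msmo1 by 1.42 ± 0.273 and Sc5d by 0.61 ± 0.129. By camera cholesterol synthesis had an adjusted p of 6.83e-10. The list median was -1.12, or -1.03 without the 3 arrays, where 7 members fell. Lipid droplet genes rose in 8 of 14 cases (11 adjusted over the list alone). G0s2 rose by 1.63 ± 0.208, Plin4 by 1.90 ± 0.298, Fitm2 by 0.81 ± 0.129 and Pnpla2 by 0.55 ± 0.0915. For lipid droplet genes camera gave an adjusted p of 2e-06 (0.324 with an estimated correlation for each of these lists). Their median went from 0.69 to 0.34 without those arrays.

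Among 22 unfolded protein response genes at ZT 9, 7 fell and 1 rose (8 and 1 adjusted over the list alone). Calr fell by 0.79 ± 0.112, Pdia6 by 1.06 ± 0.167, Pdia3 by 0.58 ± 0.107 and Sdf2l1 by 1.90 ± 0.351. By camera the unfolded protein response had an adjusted p of 0.000355. In the clock list 3 genes rose, over all genes and adjusted over the list alone. Arntl rose by 1.30 ± 0.203, Hlf by 0.63 ± 0.12 and Clock by 0.56 ± 0.109, with Cry2 at 0.27 ± 0.118. For the clock list camera gave an adjusted p of 0.0129 (0.324 with an estimated correlation for both lists). Arntl was 7.21 ± 0.302 (SD, n = 3) in the fasting phase, 5.91 ± 0.552 in the feeding phase and 5.75 ± 0.201 in ad libitum livers.

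The same comparison at ZT 9 covered lists of markers of other cells. Of 11 neutrophil genes 8 fell (11 adjusted over the list alone). S100a8 fell by 4.16 ± 1.13, Csf3r by 1.48 ± 0.413, Mpo by 2.97 ± 0.836 and Ltf by 3.50 ± 1.04. By camera the neutrophil list had an adjusted p of 2.31e-05. The median of -2.97 became 0.31 without the 3 arrays. Of 18 Kupffer cell genes 13 fell (14 adjusted over the list alone). C1qa fell by 0.93 ± 0.139, Adgre1 by 1.77 ± 0.299, Cd9 by 0.75 ± 0.129 and C1qc by 1.30 ± 0.23. For Kupffer cell genes camera gave an adjusted p of 2.58e-09 (0.324 with an estimated correlation for both lists). The median of -1.16 became -0.76. The 4 largest changes of single genes were S100a8, Cyp2b13 (4.15 ± 0.963), Sult2a3 (4.05 ± 0.835) and Ngp (-4.01 ± 1.26), and without the 3 arrays none of these passed. Altogether 2513 genes passed at ZT 9, 1037 higher and 1476 lower, or 1288 higher and 1281 lower after quantile normalization. The count was 759 without the 3 arrays and 1218 to 2961 with 1 array left out.

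At ZT 21 the fasting phase was marked by lower chaperones. The 4 largest changes were the lipoprotein lipase regulator Angptl8, which fell by 1.67 ± 0.28, Sdf2l1 by 1.66 ± 0.351 and Hyou1 by 1.43 ± 0.21, and Plin4, which rose by 1.38 ± 0.298. Of 22 unfolded protein response genes 12 fell (14 adjusted over the list alone), including Hspa5, the major chaperone BiP, by 1.13 ± 0.18, Hsp90b1 by 0.70 ± 0.114 and Pdia3 by 0.63 ± 0.107. By camera the unfolded protein response had an adjusted p of 3.22e-15 (adjusted p = 0.118 with an estimated correlation; fry adjusted p = 0.00239). Of 10 heat shock genes 3 fell (7 adjusted over the list alone). Hsp90aa1 fell by 0.96 ± 0.0977, Hsph1 by 1.36 ± 0.139 and Chordc1 by 0.92 ± 0.121, with Hspb1 at -1.05 ± 0.326. For heat shock genes camera gave an adjusted p of 2.94e-10 (adjusted p = 0.0673 with an estimated correlation).

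Markers of endothelial cells were compared between the phases at ZT 21. In fasting Kdr rose by 0.56 ± 0.105, Flt4 by 0.72 ± 0.151 and Stab2 by 0.46 ± 0.109, 3 of 12 tested (7 adjusted over the list alone), with Stab1 at 0.48 ± 0.126. By camera endothelial genes had an adjusted p of 6.48e-07 (adjusted p = 0.261 with an estimated correlation). Of 18 Kupffer cell genes 2 rose (4 adjusted over the list alone). Clec4f rose by 1.04 ± 0.213 and C1qa by 0.60 ± 0.139, with Cd5l at 1.14 ± 0.313 and Vsig4 at 0.84 ± 0.283. For Kupffer cell genes camera gave an adjusted p of 0.000448 (adjusted p = 0.632 with an estimated correlation). Their median was 0.51, and 0.32 without the 3 arrays, 1 of which belongs to the fasting phase at ZT 21. In all 326 genes passed, 161 higher and 165 lower. With 1 array left out the count ran from 81, without array 3 of the IF fasting group or array 1 of the IF feeding group at ZT 21, to 484.

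The dependence of the phase difference on time was tested as an interaction, positive where fasting minus feeding was greater at ZT 21. The 6 genes with the smallest p all had a positive interaction: the cytokine gene Il18 (1.24 ± 0.136), Crybg1 (1.44 ± 0.163), Coro1b (0.83 ± 0.0956), Mov10 (1.43 ± 0.166), Smyd3 (0.71 ± 0.0863) and the histone gene H1f2 (1.56 ± 0.193), with limma adjusted p-values of 0.000813 to 0.00133. Of 18 Kupffer cell genes 13 had a positive interaction (14 adjusted over the list alone). They included C1qa (1.54 ± 0.197), Clec4f (1.76 ± 0.302), C1qc (1.78 ± 0.325) and Adgre1 (2.31 ± 0.423), with a camera adjusted p of 2.41e-11 (adjusted p = 0.267 with an estimated correlation). Their median of 1.82 was 1.10 without the 3 arrays, where 3 passed. Neutrophil genes had 1 of 11 past the threshold (11 adjusted over the list alone), S100a8 at 5.56 ± 1.6 (lost in 15 of 18 fits with 1 array left out), with Csf3r at 1.90 ± 0.584, Ngp at 5.55 ± 1.79 and Mpo at 3.66 ± 1.18. By camera the neutrophil list had an adjusted p of 8.3e-06 (adjusted p = 0.267 with an estimated correlation). The median of 3.84 became -0.19 without the 3 arrays.

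Fatty acid oxidation had 8 of 32 genes with a negative interaction of phase and time (18 adjusted over the list alone), that is, a smaller fasting rise at ZT 21: Cpt2 (-0.78 ± 0.117), Acot4 (-1.53 ± 0.253), Acot3 (-2.29 ± 0.462) and Etfdh (-0.55 ± 0.117), with a camera adjusted p of 7.92e-11 (adjusted p = 0.267 with an estimated correlation) and a median of -0.64, or -0.27 without the 3 arrays. For cholesterol synthesis 6 of 19 were positive (14 adjusted over the list alone). They included Fdps (1.48 ± 0.36), Hmgcs1 (1.34 ± 0.359), Cyp51 (1.70 ± 0.473) and Nsdhl (1.05 ± 0.3, lost in 10 of 18 fits with 1 array left out), with a camera adjusted p of 3.21e-07 (adjusted p = 0.267 with an estimated correlation). For heat shock 4 of 10 were negative (6 adjusted over the list alone). They included Hsph1 (-1.19 ± 0.197), Hsp90aa1 (-0.69 ± 0.138), Chordc1 (-0.81 ± 0.171) and Hspd1 (-0.45 ± 0.105), with a camera adjusted p of 2.4e-05 (adjusted p = 0.267 with an estimated correlation). Without the 3 arrays 0 cholesterol and 1 heat shock gene passed in limma, and both lists were still called by camera. The clock list was not called as a set (camera adjusted p = 0.135), with 1 member positive and 3 negative (1 and 6 adjusted over the list alone). They included Nr1d2 (0.62 ± 0.165), Arntl (-1.39 ± 0.287), Clock (-0.62 ± 0.154) and Cry1 (-0.80 ± 0.228, lost in 12 such fits). Over all genes 1192 passed, 814 positive and 378 negative, or 673 and 465 after quantile normalization. The count was 167 without the 3 arrays and 576 to 2130 with 1 array left out.

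Long-term IF was compared with ad libitum feeding through the IF term, which sets the IF feeding phase against ad libitum livers over both times. No gene reached the threshold in the additive model, against 12 with array weights, 19 in the 6-group model and 53 with both IF phases against ad libitum feeding. The 10 with the smallest p included the integrin Itga6 (0.59 ± 0.0959), Gimd1 (0.59 ± 0.1), Smpd3 (0.79 ± 0.148), Itih5 (0.76 ± 0.149), Hpf1 (0.39 ± 0.0744) and Nudt7 (0.34 ± 0.0634), which were higher in IF, and Bmp2 (-0.47 ± 0.0845), Ttc7b (-0.42 ± 0.0742), Coq10a (-0.30 ± 0.057) and Kif1b (-0.27 ± 0.0469), which were lower. Their limma adjusted p-values were 0.0952 to 0.116. Itga6 was between 6.15 and 6.65 on the 6 ad libitum arrays and between 6.57 and 7.39 on the 12 IF arrays. By limma the count was 0 after adjustment and 1377 at an unadjusted p under 0.05, where 705 would be called by chance; camera called 15 of 33 lists, 0 with an estimated correlation, and fry none.

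Endothelial genes were lower as a set in the IF feeding phase. Of 12, 0 passed over all genes and 7 were lower adjusted over the list alone. Oit3 (-0.37 ± 0.0755), Kdr (-0.39 ± 0.0885), Flt4 (-0.53 ± 0.133) and Stab2 (-0.34 ± 0.0993) led it. Their camera adjusted p was 1.03e-05 (adjusted p = 0.613 with an estimated correlation; fry adjusted p = 0.149). Without the 3 arrays the median went from -0.33 to -0.41 and 5 members fell, among them Oit3 by 0.45, Kdr by 0.52, Flt4 by 0.71 and Stab2 by 0.50 (limma adjusted p of 0.0233 to 0.0366). Bmp2 also passed there at -0.55, as did Itga6 at 0.64, Gimd1 at 0.68, Hpf1 at 0.42 and Ttc7b at -0.36, among 32 genes in all.

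Bile acid synthesis genes had a median of -0.10 in IF against ad libitum feeding, with 0 of 17 past the threshold and 2 lower adjusted over the list alone: Cyp7b1 (-0.64 ± 0.153) and Cyp27a1 (-0.20 ± 0.0523), the entry enzymes of the alternative pathway, with Cyp7a1 at -0.71 ± 0.306 and Cyp8b1 at -0.57 ± 0.277. The camera adjusted p was 0.00499 (adjusted p = 0.613 with an estimated correlation; fry adjusted p = 0.149). At ZT 21 Cyp7a1 was 10.17 ± 0.00794 (SD, n = 3) in the IF feeding phase and 11.31 ± 0.139 in ad libitum livers. Its IF difference was -1.03 without the 3 arrays and -0.97 without the 2 at ZT 9, which held 10.83 and 11.46. Bile acid transport and sensing was not called (camera adjusted p = 0.0559), with 1 of 21 higher and 2 lower adjusted over the list alone and 0 over all genes; Abcc3 stood at -0.38 ± 0.0938, Atp8b1 at 0.36 ± 0.103, Abcg8 at -0.32 ± 0.0941 and Gpbar1, the bile acid receptor TGR5, at -0.19 ± 0.0694.

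Other lists called in IF moved with the arrays that stand apart. Neutrophil genes had a median of 1.40, with 0 of 11 past the threshold. For the neutrophil list camera gave an adjusted p of 1.89e-05 (adjusted p = 0.613 with an estimated correlation). Ltf (1.80 ± 0.886), Mpo (1.38 ± 0.723), Cxcr2 (0.95 ± 0.517) and Elane (1.48 ± 0.817) led it, and the median was -0.23 without the 3 arrays. Acute phase genes had 0 of 25 past the threshold and a median of 0.17. By camera acute phase genes had an adjusted p of 7.45e-05 (adjusted p = 0.613 with an estimated correlation). Orm3 stood at 1.78 ± 0.498, Orm1 at 0.39 ± 0.155, Orm2 at 1.14 ± 0.55 and Apcs at 0.72 ± 0.406, and the median without those arrays was -0.10. Fatty acid oxidation had a median of -0.24 with 0 of 32 past it. For fatty acid oxidation camera gave an adjusted p of 1.45e-05 (adjusted p = 0.613 with an estimated correlation). Plin5 stood at -0.56 ± 0.163, Fabp1 at -0.26 ± 0.102, Acot3 at -0.91 ± 0.392 and Eci1 at -0.26 ± 0.122, and the median became 0.0066.

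Xenobiotic metabolism had 0 of 25 past the threshold and 5 lower adjusted over the list alone: Cyp2a4 (-1.38 ± 0.32), Ces2a (-0.51 ± 0.121), Cyp3a25 (-0.65 ± 0.175) and Cyp2a5 (-1.01 ± 0.279) led it. By camera xenobiotic metabolism had an adjusted p of 2.97e-05 (adjusted p = 0.613 with an estimated correlation). Its median of -0.20 was -0.017 without the 3 arrays. Cholesterol synthesis had 0 of 19 past the threshold and a median of 0.22. For cholesterol synthesis camera gave an adjusted p of 0.0031 (adjusted p = 0.663 with an estimated correlation). Srebf2 stood at 0.22 ± 0.116, Mvk at 0.30 ± 0.18, Lss at 0.46 ± 0.292 and Msmo1 at 0.39 ± 0.243, and the median became -0.0041. By fry the adjusted p-values of these 5 lists were 0.348 to 0.557. Of the genes always named, Abcb11 (-0.04 ± 0.116), Slc10a1 (-0.03 ± 0.0507), Nr1h4 (-0.0050 ± 0.0817), Nr0b2 (0.04 ± 0.173), Baat (-0.15 ± 0.141), Fgf21 (-0.43 ± 0.257), Cpt1a (-0.09 ± 0.0901), Pck1 (-0.07 ± 0.0983), Srebf1 (0.22 ± 0.0983), Arntl (0.06 ± 0.248), Dbp (-0.028 ± 0.136) and Lepr (-0.94 ± 0.215, limma adjusted p = 0.142) did not pass.

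The rule the authors describe, with its likelihood ratio test over the whole model, selected 61 genes for IF, 40 higher and 21 lower. Among those named in the text it took Itga6, Gimd1, Smpd3, Itih5, Orm3, Stfa2l1, S100a6, Mybl1, Krt18, Dhrs9 and Sdf2l1 as higher, and Cyp2a4, Cyp2a5, Cyp3a25, Cyp7b1, Plin4, Cd7 and Lepr as lower. The first step kept 6423 genes at a false discovery rate under 0.3, a test that time of day and fasting can pass as well as IF, and 1383 of them had p under 0.05. After Benjamini-Hochberg adjustment of the same linear model p, 1 gene remained under 0.05. The rule selected 99 genes without the 3 arrays, 34 of them shared with the first 61.

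At ZT 9 IF feeding livers differed from ad libitum livers in 650 genes, 400 higher and 250 lower (320 and 331 after quantile normalization). The count was 16 to 1905 with 1 array left out and 0 with only these 2 groups. The SEs pool all groups. Root mean square deviations from the group mean were 0.17 to 0.28 on these IF arrays and 0.12 to 0.20 elsewhere. The 4 largest changes were falls of Cyp2b13 (-3.78 ± 0.963) and Hao2 (-3.72 ± 0.666), both female-biased liver genes, and rises of the neutrophil protease Ctsg (3.45 ± 0.944) and Stfa2l1 (3.43 ± 0.925). With 1 array left out Ctsg and Stfa2l1 did not pass in 16 of 18 fits each, nor Cyp2b13 in 11. Of 25 xenobiotic genes 7 fell (16 adjusted over the list alone). Cyp2a4 fell by 2.33 ± 0.335, Cyp2a5 by 1.76 ± 0.301, Gstm1 by 0.99 ± 0.178 and Ces2a by 0.69 ± 0.15. By camera xenobiotic metabolism had an adjusted p of 5.25e-09. Of 12 female-biased genes 5 fell, over all genes and adjusted over the list alone, among them Acot3 by 2.12 ± 0.327 and Cyp2b9 by 0.99 ± 0.243. For female-biased genes camera gave an adjusted p of 0.000215. Fatty acid oxidation fell in 7 of 32 (23 adjusted over the list alone). Acot4 fell by 1.11 ± 0.179, Acaa1b by 1.28 ± 0.296 and Cpt2 by 0.34 ± 0.0826. By camera fatty acid oxidation had an adjusted p of 1.98e-12 (0.258 with an estimated correlation for each of these lists).

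Cell cycle genes rose at ZT 9 in 5 of 22 cases (12 adjusted over the list alone). Top2a rose by 1.31 ± 0.277, Aurkb by 0.78 ± 0.175, Mki67 by 1.47 ± 0.329 and Kif11 by 1.06 ± 0.239. For the cell cycle list camera gave an adjusted p of 4.37e-08 (adjusted p = 0.258 with an estimated correlation). Acute phase genes rose in 2 of 25 (9 adjusted over the list alone). Lcn2 rose by 2.18 ± 0.528 and Cp by 0.42 ± 0.112 (lost in 15 of 18 fits with 1 array left out), with Orm2 at 2.24 ± 0.679 and Apcs at 1.52 ± 0.493. By camera acute phase genes had an adjusted p of 7.78e-09 (adjusted p = 0.307 with an estimated correlation). Neutrophil genes had 0 of 11 past the threshold over all genes and 11 higher adjusted over the list alone, with S100a8 at 4.04 ± 1.13, Csf3r at 1.44 ± 0.413, Ltf at 3.55 ± 1.04 and S100a9 at 2.60 ± 0.769. For the neutrophil list camera gave an adjusted p of 4.37e-08 (adjusted p = 0.259 with an estimated correlation; fry adjusted p = 0.0353). Without the 3 arrays, which leaves 1 IF feeding array at this time, limma called 0 genes. List medians then stood at 0.79 for the cell cycle (0.56 before), -0.91 for female-biased genes (-0.79), -0.30 for xenobiotic metabolism (-0.62), -0.17 for fatty acid oxidation (-0.48), -0.019 for the acute phase (0.49) and -0.20 for neutrophils (3.14).

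At ZT 21 IF livers in the feeding phase were compared with ad libitum livers. The 4 largest changes were the chemokine Ccl5, which fell by 2.75 ± 0.54 (6.71-fold), the T cell receptor chain Cd3g by 2.07 ± 0.39 and Cd7 by 1.64 ± 0.209, and the water channel Aqp4, which rose by 1.71 ± 0.34. When 1 array was left out in turn, Cd7 passed in all 18 fits, but Ccl5 did not pass in 14, Aqp4 in 15 and Cd3g in 8. Ccl5 passed without any 1 array of the IF feeding group at ZT 9 or array 1 of the IF fasting group at ZT 21, and its highest limma adjusted p in the other fits was 0.167. The highest was 0.178 for Aqp4 and 0.148 for Cd3g. Of 9 T and NK cell genes 2 fell, Cd3g and Nkg7 (by 1.58 ± 0.281), and 9 were lower adjusted over the list alone, with Gzmb at -1.11 ± 0.227 and Cd8b1 at -0.95 ± 0.249. By camera T and NK cell genes had an adjusted p of 9.47e-10 (adjusted p = 0.148 with an estimated correlation; fry adjusted p = 0.00678). Kupffer cell genes fell in 2 of 18 cases (8 adjusted over the list alone). C1qa fell by 0.84 ± 0.139 and Clec4f by 1.24 ± 0.213, with Cd5l at -1.28 ± 0.313 and Adgre1 at -1.05 ± 0.299. For Kupffer cell genes camera gave an adjusted p of 2.6e-08 (adjusted p = 0.18 with an estimated correlation).

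Of 12 endothelial genes at ZT 21 none passed in limma over all genes and 9 were lower adjusted over the list alone, led by Kdr (-0.50 ± 0.105), Stab2 (-0.50 ± 0.109), Flt4 (-0.69 ± 0.151) and Stab1 (-0.52 ± 0.126), with a camera adjusted p of 1.33e-09 (adjusted p = 0.148 with an estimated correlation; fry adjusted p = 0.00678). Antigen presentation by MHC class II had 1 of 6 that fell (5 adjusted over the list alone), the costimulator Cd86 by 0.85 ± 0.129, with H2-Ab1 at -1.35 ± 0.327, H2-Eb1 at -1.15 ± 0.3 and H2-Aa at -1.22 ± 0.336. By camera MHC class II genes had an adjusted p of 1.17e-06 (adjusted p = 0.148 with an estimated correlation). The list mean of T and NK genes was between -0.49 and -0.36 on the 3 IF feeding arrays and between 0.37 and 0.77 on the 3 ad libitum arrays. Altogether 45 genes passed, 10 higher and 35 lower. With the 3 arrays left out, none of which belongs to these groups, 229 did. With 1 array left out the count ran from 3, without array 2 of the IF feeding group at ZT 21, to 131, without array 1 of the IF feeding group at ZT 9.

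The dependence of the IF difference on time was tested as an interaction, negative where IF feeding minus ad libitum was lower at ZT 21 than at ZT 9. The 6 genes with the smallest p were all negative: the complement genes C6 (-2.64 ± 0.309) and C1qa (-1.42 ± 0.197), the NK cell gene Nkg7 (-3.27 ± 0.398), the inflammasome protease Casp1 (-1.53 ± 0.19), its substrate Il18 (-1.02 ± 0.136) and Parp14 (-1.53 ± 0.208), with limma adjusted p-values of 0.00262 to 0.00454. C6 was 9.55 ± 0.499 (SD, n = 3) in the IF feeding phase and 7.84 ± 0.176 in ad libitum livers at ZT 9, and 7.53 ± 0.0415 and 8.46 ± 0.202 at ZT 21. Of 9 T and NK genes 3 had a negative interaction (7 adjusted over the list alone), Nkg7, Gzmb (-1.96 ± 0.322) and Cd3g (-2.53 ± 0.552), with Cd8a at -1.09 ± 0.302 and a camera adjusted p of 3.21e-07 (adjusted p = 0.21 with an estimated correlation).

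Kupffer cell genes had a negative IF by time interaction in 8 of 18 (14 adjusted over the list alone). They included Adgre1 (-2.06 ± 0.423), Cd5l (-2.09 ± 0.442) and Clec4f (-1.40 ± 0.302), with a camera adjusted p of 1.19e-09 (adjusted p = 0.21 with an estimated correlation). For neutrophils 0 of 11 passed in limma over all genes and 9 were negative adjusted over the list alone. For the neutrophil list camera gave an adjusted p of 2.55e-05 (adjusted p = 0.304 with an estimated correlation; fry adjusted p = 0.0818). Csf3r stood at -1.74 ± 0.584, S100a8 at -4.74 ± 1.6, Ngp at -4.76 ± 1.79 and S100a9 at -2.88 ± 1.09. Fatty acid oxidation was positive in 3 of 32 (16 adjusted over the list alone). They included Acot4 (1.45 ± 0.253), Acot3 (2.41 ± 0.462) and Cpt2 (0.54 ± 0.117), with Acaa1b at 1.48 ± 0.419. By camera fatty acid oxidation had an adjusted p of 1.19e-09 (adjusted p = 0.251 with an estimated correlation). Without the 3 arrays the medians were -1.72 for T and NK cells (-1.14 before), -0.99 for Kupffer cells (-1.49), -0.010 for neutrophils (-3.47) and 0.20 for fatty acid oxidation (0.55). Over all genes 700 passed, 175 positive and 525 negative, or 260 and 389 after quantile normalization. The count was 147 without the 3 arrays and 162 to 1948 with 1 array left out.

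**Figure D4:**
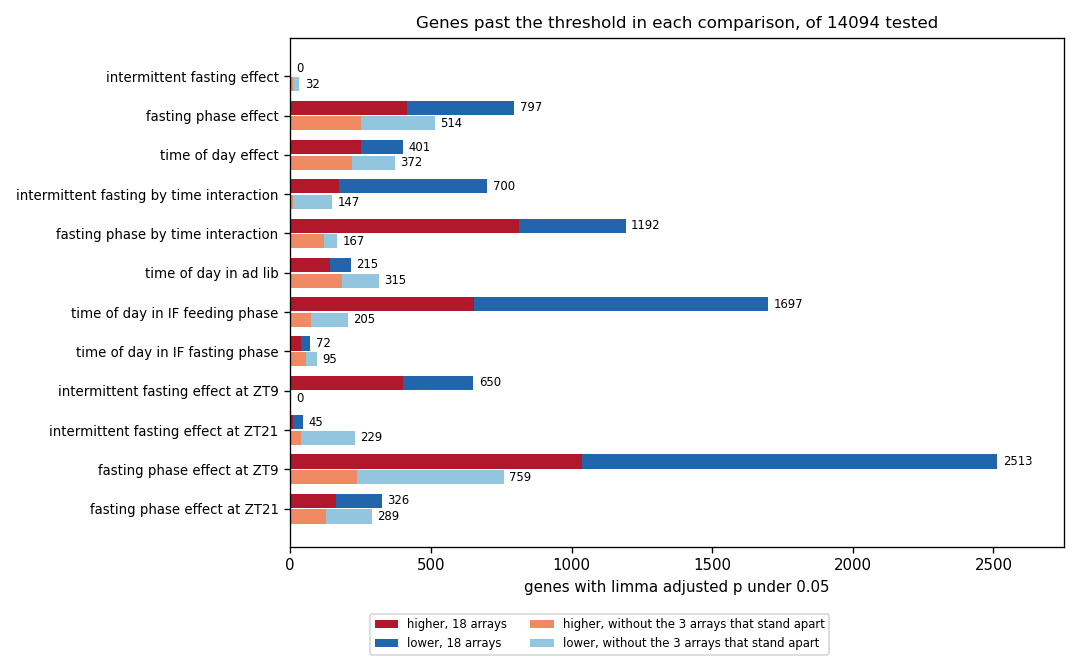
Genes with a limma adjusted p under 0.05 (horizontal axis, starting at 0) in each of the 12 comparisons (vertical axis), with stacked bars for higher and lower genes, in darker colours for all 18 arrays and in paler colours without the 3 arrays that stand apart. The fasting phase comparison at ZT 9 goes from 2513 to 759 genes and the IF comparison at ZT 9 from 650 to 0, while the time of day effect goes from 401 to 372.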

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

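All tests of explanations here, and leaving out arrays, were chosen after the result was seen. The interaction tests and other splits were planned before the data were examined. What singles out the results here is a difference between groups: the effect of IF, or of the fasting phase, was not the same at ZT 9 and ZT 21 by limma's interaction test with Benjamini-Hochberg adjustment (camera for gene lists). In the IF groups the time since food was removed or given also differed between ZT 9 and ZT 21. It cannot be told apart from time of day here.

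The IF difference depended on time in 700 genes. Negative interactions on the log2 scale, with the IF difference lower at ZT 21, were found for Nkg7 (-3.27), Ccl5 (-3.07), C6 (-2.64), Cd3g (-2.53), Cd5l (-2.09), Adgre1 (-2.06), Gzmb (-1.96), Cd7 (-1.93), Casp1 (-1.53), Parp14 (-1.53), C1qa (-1.42), Clec4f (-1.40), Lepr (-1.30), Crybg1 (-1.12), H1f2 (-1.12), Il18 (-1.02), Mov10 (-0.97) and Smyd3 (-0.49). Positive ones were found for Cyp2b13 (5.32), Sult2a3 (4.95), Hao2 (4.28), Acot3 (2.41), Aqp4 (2.22), Glod5 (1.75), Acot4 (1.45) and Cpt2 (0.54). List medians were -3.47 for neutrophils, -1.49 for Kupffer cells, -1.14 for T and NK cells and 0.55 for fatty acid oxidation. Camera called none of these lists with an estimated correlation (adjusted p = 0.21 to 0.304), and without the 3 arrays that stand apart their medians were -0.010, -0.99, -1.72 and 0.20. Without those arrays 147 genes passed in all. Of the 26 named here 15 passed, and the others stood at -1.25 (Adgre1), -1.15 (Cd5l), -1.06 (Lepr), -0.93 (H1f2), -0.69 (Clec4f), 4.78 (Sult2a3), 2.34 (Cyp2b13), 2.18 (Hao2), 1.52 (Glod5), 1.075 (Aqp4) and 0.38 (Cpt2), with limma adjusted p-values of 0.0529 to 0.233.

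The difference between fasting and feeding depended on time in 1192 genes. Positive interactions were found for S100a8 (5.56), Saa2 (5.44), C6 (2.38), Nkg7 (2.37), Adgre1 (2.31), S100a6 (1.86), C1qc (1.78), Clec4f (1.76), Cyp51 (1.70), H1f2 (1.56), C1qa (1.54), Fdps (1.48), Crybg1 (1.44), Mov10 (1.43), Upp2 (1.41), Hmgcs1 (1.34), Parp14 (1.25), Il18 (1.24), Nsdhl (1.05), Casp1 (1.02), Cd7 (1.02), Smpd3 (0.91), Coro1b (0.83), Smyd3 (0.71) and Nr1d2 (0.62). Negative ones were found for Cyp2b13 (-4.73), Sult2a3 (-4.57), Hao2 (-3.20), Acot3 (-2.29), Ppp1r3c (-1.66), Acot4 (-1.53), Arntl (-1.39), Hsph1 (-1.19), Chordc1 (-0.81), Cry1 (-0.80), Cpt2 (-0.78), Baat (-0.76), Hsp90aa1 (-0.69), Clpx (-0.67), Clock (-0.62), Etfdh (-0.55) and Hspd1 (-0.45). List medians were 3.84 for neutrophils, 1.82 for Kupffer cells, 0.82 for cholesterol synthesis, -0.64 for fatty acid oxidation and -0.55 for heat shock. Camera called none of these lists with an estimated correlation (adjusted p = 0.267 for each), and without the 3 arrays their medians were -0.19, 1.10, 0.998, -0.27 and -0.46. Without those arrays 167 genes passed in all. Of the 42 named here 18 passed, and the positive ones that did not were S100a8 (0.63), Saa2 (1.73), Adgre1 (1.26), S100a6 (1.11), C1qc (1.22), Cyp51 (1.76), Fdps (1.53), Upp2 (1.40), Hmgcs1 (1.40), Parp14 (1.06), Nsdhl (1.07) and Smpd3 (0.87). The negative ones were Cyp2b13 (-1.69), Sult2a3 (-4.78), Hao2 (-0.54), Ppp1r3c (-1.13), Chordc1 (-0.69), Cry1 (-0.97), Baat (-0.58), Hsp90aa1 (-0.48), Clpx (-0.86), Clock (-0.49), Etfdh (-0.39) and Hspd1 (-0.30).

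Arrays 2 and 3 of the IF feeding group at ZT 9 held high neutrophil and acute phase transcripts. A wrong time label is argued against by Dbp, which was at least 9.28 on both arrays, while the ZT 21 arrays lay between 6.62 and 7.39. A wrong phase label is argued against by Srebf1, at least 9.70 on both against 8.67 to 9.003 on the fasting arrays. A lower share of hepatocytes would raise markers of every other cell type alike, yet the neutrophil list rose more than the endothelial list by 3.08 ± 0.997 (SE). Infiltration or illness in these mice may account for the pattern and was not tested.

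T and NK cell and endothelial lists were lower in the IF feeding phase than in ad libitum livers at ZT 21 by camera at its preset correlation, with 2 of 9 and 0 of 12 genes past limma's threshold over all genes and a camera adjusted p = 0.148 for each with an estimated correlation. A higher share of hepatocytes would lower both lists alike, so the further fall of the T and NK list, by -0.63 ± 0.255 (SE) relative to the endothelial list, argues against it as the whole explanation for T and NK cells. It stays open for the endothelial list: the stellate cell list, with Colec11 at -0.51 and Colec10 at -0.48, differed from it by 0.247 ± 0.15 (SE), less than 2 SE, although the 4 cholangiocyte genes were higher (Krt19 0.42, Krt7 0.39, Sox9 0.25 and Epcam 0.14, none past limma's threshold). Scaling is argued against by a T and NK median of -0.90 after quantile normalization against -0.92 as deposited. Cd3g had a mean of 6.11 in ad libitum livers at ZT 21 and of 4.04 to 5.15 in the other 5 groups, and at ZT 9 Nkg7 was higher in the IF feeding phase (7.70) than in ad libitum livers (6.01). Whether the cells or their expression are high in ad libitum livers at ZT 21 or low under IF stays open.

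Arntl and Clock were higher in the fasting phase than in the feeding phase at ZT 9. Collection at another hour that moved every clock gene by the same share of its time of day range is argued against by a median share of 0.0459 over 12 clock genes beside 0.425 for Arntl (SE 0.0665). A shift in hours need not move all genes by 1 share, so a form of it stays open. The arrays that stand apart are argued against by an Arntl difference of 1.69 without them (limma adjusted p = 0.00143). An effect of fasting on these genes may be the explanation and was not tested apart from these.

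Other splits of the arrays were counted for each comparison. Of 100 splits, the real one included, no other reached the count for the fasting phase (797, highest other 407). This held for time of day too (401, highest other 114). Both argue against chance at this number of splits. The counts of the IF by time (700, highest other 169) and fasting phase by time (1192, highest other 774) interactions were not reached either. Those splits exchanged labels within a time, so they test for any difference, not for the interaction alone. For the IF effect the real count was 0, which all 100 splits must reach, so they say nothing about chance there. The highest others, 195 here and 407 for the fasting phase, exchanged whole groups at ZT 21 and so measured interactions with time. Each of the 7 comparisons within a time or group has 10 splits, too few for a share under 0.05. Their highest other count was 5 (time in ad libitum) and 0 elsewhere, against real counts of 45 to 2513.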

How the results depend on the processing

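Leaving out 2 or 3 arrays that stand apart was chosen after the result was seen, and all other alternatives before the data were examined. Counts are of genes with a limma adjusted p under 0.05, and gene list tests are by camera. With all arrays the counts were 0 for the IF effect, 797 for the fasting phase, 401 for time of day, 700 for the IF by time interaction, 1192 for the fasting phase by time interaction, 215 for time in ad libitum feeding, 1697 for time in the IF feeding phase, 72 for time in the IF fasting phase, 650 for IF at ZT 9, 45 for IF at ZT 21, 2513 for the fasting phase at ZT 9 and 326 for the fasting phase at ZT 21, with 186 gene list tests. Each of these 13 counts stayed within 1.5 times under quantile normalization and under a trended and robust variance. Of 351 values of named genes, 348 kept direction and side of the threshold under quantile normalization, 325 with the other variance, 336 with no filter, 303 with array weights and 282 with every transcript cluster. Causes not named below were not tested. As detection calls were not used, how far background limits the weaker genes is not known.

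Counts that moved by more than 1.5 times were, with array weights, 12 for the IF effect, 2309 for the IF by time interaction, 2498 for the fasting phase by time interaction, 696 for time in ad libitum feeding, 3167 for time in the IF feeding phase, 501 for time in the IF fasting phase, 2190 for IF at ZT 9, 489 for IF at ZT 21 and 989 for the fasting phase at ZT 21. With no filter, which tests more genes, they were 37 for time in the IF fasting phase, 427 for IF at ZT 9, 24 for IF at ZT 21 and 202 for the fasting phase at ZT 21, and with the stricter filter, which tests fewer genes, 120 for time in the IF fasting phase. With every transcript cluster as a feature, which tests more of them, they were 408 for the fasting phase, 288 for the IF by time interaction, 581 for the fasting phase by time interaction, 27 for time in the IF fasting phase, 157 for IF at ZT 9, 17 for IF at ZT 21 and 104 for the fasting phase at ZT 21. With only the groups compared they were 482 for the fasting phase, 323 for the IF by time interaction, 737 for the fasting phase by time interaction, 77 for time in ad libitum feeding, 405 for time in the IF feeding phase, 21 for time in the IF fasting phase, 0 for IF at ZT 9, 83 for IF at ZT 21 and 601 for the fasting phase at ZT 9. The 6-group model gave 19 for the IF effect and 1398 for the fasting phase, and both IF phases against ad libitum feeding gave 53 for the IF effect. The likelihood ratio rule of the methods gave 61 for the IF effect, and its linear model p after Benjamini-Hochberg adjustment gave 1. Asking also for 1.5-fold left 151 for the fasting phase and 76 for time of day. Of 396 list tests 3 passed with an estimated correlation and 109 by fry.

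Without arrays 2 and 3 of the IF feeding group at ZT 9 the counts that moved were 24 for the IF effect, 98 for the IF by time interaction, 231 for the fasting phase by time interaction, 182 for time in the IF feeding phase, 120 for time in the IF fasting phase, 0 for IF at ZT 9, 159 for IF at ZT 21, 667 for the fasting phase at ZT 9 and 532 for the fasting phase at ZT 21. Without array 1 of the IF fasting group at ZT 21 as well they were 32 for the IF effect, 514 for the fasting phase, 147 for the IF by time interaction, 167 for the fasting phase by time interaction, 205 for time in the IF feeding phase, 0 for IF at ZT 9, 229 for IF at ZT 21 and 759 for the fasting phase at ZT 9. Both leave 1 array in the IF feeding group at ZT 9, assumed to vary like other groups. Of the named genes 239 kept direction and side of the threshold without the 3 arrays, 76 lost it, 32 gained it and 4 reversed. Of 62 lists 44 kept it, 7 lost it and 11 reversed.

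The genes that reversed, with the same value in both cases, were S100a9 by time in the IF feeding phase (0.033), Ctsg for IF at ZT 9 (-0.0024), and Ngp (0.088) and Ltf (0.31) for the fasting phase at ZT 9. List medians that reversed in the IF effect are given without 2 and without 3 arrays. For cholesterol synthesis they were 0.010, not reversed, and -0.0041. The others were 0.016 and 0.0066 for fatty acid oxidation, -0.12 and -0.099 for the acute phase, and -0.29 and -0.23 for neutrophils. Those in the fasting phase were 0.054 and -0.097 for Kupffer cells, where camera's direction reversed in both cases, and 0.58 and 0.21 for neutrophils. Neutrophils also had -0.010 in the IF by time interaction (2 arrays, where only camera's direction reversed), -0.19 in the fasting phase by time interaction (3 arrays), 0.033 by time in the IF feeding phase, -0.20 for IF at ZT 9 and 0.31 for the fasting phase at ZT 9, and the acute phase had -0.019 for IF at ZT 9 (the last 4 alike in both cases). With both IF phases against ad libitum feeding the medians of fatty acid oxidation (0.026) and cholesterol synthesis (-0.024) reversed.

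The replicate numbers do not pair the mice across groups. Deviations from the group means of the 45 same-numbered pairs of arrays had correlations of -0.46 to 0.389 (median -0.029), 9 of them over 0.1, and 5 of 18 arrays correlated best with their own number. With the replicate number as a block the count moved by more than 1.5 times only for IF at ZT 21, from 45 to 17. The others included 647 for the fasting phase and 354 for time of day. Of the named genes 331 kept direction and side of the threshold under the block.

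Each array was also left out in turn (AL, fed and fast stand for ad libitum and the IF feeding and fasting phases, followed by the ZT, and brackets give counts without the array named). Counts ran from 0 to 4 for the IF effect (AL 9 array 2: 1, AL 21 array 3: 1, fed 9 array 2: 1, fed 9 array 3: 1, fast 21 array 1: 4). For the fasting phase they ran from 437 to 857 (fed 9 array 1: 522, fed 9 array 2: 528, fast 9 array 1: 437, fast 9 array 2: 470). For time of day they ran from 311 to 416. For the IF by time interaction they ran from 162 to 1948 (AL 9 array 1: 162, AL 9 array 3: 430, AL 21 array 2: 258, fed 9 array 1: 1948, fed 9 array 2: 275, fed 9 array 3: 458, fed 21 array 2: 288, fed 21 array 3: 239). For the fasting phase by time interaction they ran from 576 to 2130 (fed 9 array 1: 2130, fed 9 array 2: 617, fast 21 array 1: 701, fast 21 array 3: 684, fast 9 array 1: 668, fast 9 array 2: 576, fed 21 array 1: 754, fed 21 array 2: 637, fed 21 array 3: 749). For time in ad libitum feeding they ran from 114 to 286 (AL 9 array 1: 114, AL 9 array 2: 117, AL 9 array 3: 137, AL 21 array 3: 116). For time in the IF feeding phase they ran from 691 to 2565 (fed 9 array 1: 2565, fed 9 array 2: 691, fed 21 array 1: 1084, fed 21 array 2: 881, fed 21 array 3: 944). For time in the IF fasting phase they ran from 23 to 110 (fed 9 array 1: 110, fast 21 array 2: 31, fast 21 array 3: 24, fast 9 array 1: 26, fast 9 array 2: 23, fed 21 array 1: 47). For IF at ZT 9 they ran from 16 to 1905 (AL 9 array 1: 16, AL 9 array 2: 191, AL 9 array 3: 25, fed 9 array 1: 1905, fed 9 array 2: 22, fed 9 array 3: 254, fed 21 array 3: 426). For IF at ZT 21 they ran from 3 to 131 (AL 9 array 3: 27, AL 21 array 1: 20, AL 21 array 2: 8, AL 21 array 3: 22, fed 9 array 1: 131, fed 9 array 2: 81, fast 21 array 3: 14, fast 9 array 1: 23, fast 9 array 2: 21, fed 21 array 1: 17, fed 21 array 2: 3, fed 21 array 3: 10). For the fasting phase at ZT 9 they ran from 1218 to 2961 (fed 9 array 2: 1218, fast 9 array 1: 1530, fast 9 array 2: 1397). For the fasting phase at ZT 21 they ran from 81 to 484 (fast 21 array 1: 170, fast 21 array 2: 130, fast 21 array 3: 81, fed 21 array 1: 81, fed 21 array 2: 100, fed 21 array 3: 153). For gene list tests they ran from 168 to 191. Of the values of named genes 5809 kept direction and side of the threshold, 432 lost it and 77 gained it, and 1095, 15 and 6 of the list values did. No gene or list reversed when 1 array was left out.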

Other observations

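Leaving out the arrays that stand apart, and singling out array 1 below, were chosen after the data were seen. Lists of proliferation and antigen presentation, fixed before the data were examined, also differed between the phases at ZT 9. Of 22 cell cycle genes 14 fell in fasting and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.79 and a camera adjusted p of 1.14e-06 (adjusted p = 0.324 with an estimated correlation); without the 3 arrays 10 fell and the median was -0.94. Of 6 genes of antigen presentation by MHC class II 5 fell, over all genes and adjusted over the list alone, with a median of -1.25 (camera adjusted p = 0.000105; adjusted p = 0.324 with an estimated correlation), or -1.91 without the 3 arrays. The interferon response fell in 9 of 18 (10 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 7.62e-05; adjusted p = 0.324 with an estimated correlation). Oxidative phosphorylation rose in 10 of 39 (15 adjusted over the list alone) with a median of 0.19 (camera adjusted p = 7.52e-07; adjusted p = 0.324 with an estimated correlation), and 0 of them passed in limma without the 3 arrays, where the median was 0.074. At ZT 21 ribosome biogenesis fell in fasting in 2 of 27 genes (5 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 8.58e-06; adjusted p = 0.393 with an estimated correlation).

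Array 1 of the IF feeding group at ZT 9, the one without high neutrophil genes (-0.82), had list mean deviations of 0.90 for MHC class II, 0.62 for extracellular matrix, 0.59 for the interferon response, 0.67 for the cell cycle and 0.79 for T and NK cells.

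Lepr, the leptin receptor gene that carries the db mutation, was at log2 values of 6.05, 6.78 and 6.73 in ad libitum livers at ZT 21 and 5.62, 5.95 and 5.42 at ZT 9. In the IF feeding phase it was 5.17, 4.53 and 5.11 at ZT 21 and 5.14, 5.30 and 5.68 at ZT 9. The IF by time interaction was -1.30 (limma adjusted p = 0.0283), and -1.06 without the 3 arrays that stand apart, where it did not pass (limma adjusted p = 0.233).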
